A study of Mus musculus with 2 samples.

How the data were processed

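H3K4me2 ChIP-seq was carried out on limb tissue of mouse embryos (strain label B6NTac;B6NCrl/Lap, 14.5 days, both sexes), with 2 biological replicates of 24 and 34 pooled embryos and DNA fragments of 300 to 500 bp. Per the labels, both samples were immunoprecipitated for H3K4me2 and form 1 group. The aligner and the peak caller and their versions are not given in the sources used here. The deposited notes say that the peak list of each replicate was made from its filtered alignment and 1 control alignment. The pooled list was made from the alignments of both replicates and 2 control alignments, and the replicated list was derived from the 3 other lists. The control libraries were not analysed here.

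All lists are narrowPeak files on mm10. The deposited score column is a whole number from 10 to 1000, scaled within each list by the authors. The deposited signal column is a ratio, read here as fold enrichment over the control; the deposited notes do not name its unit. The p-value and q-value columns deposited by the authors are minus log10 values (−log10 p and −log10 q). The lowest −log10 p was just above 2, so the lists include peaks with an authors' q-value above 0.01. The offset column gives the summit position in bp from the peak start and was not used. Values of the replicated list are those of the pooled list, in which all 35167 of its intervals on assembled chromosomes were found with the same start and end. Of these, 2898 do not meet even the rule of any overlap with a peak in both replicates. With at least 50% of either peak required, 2974 do not, and with at least 50% of the pooled peak 9423 do not. The exact rule behind the list therefore remains unknown, and a replicated peak is not always found in both replicate lists.

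Depth is unknown, as read counts were not analysed here. The precision of a percentage was given as an exact (Clopper-Pearson) 95% interval over peaks or genes, which covers counting error only; neighbouring peaks and genes are not independent. With 2 replicates, spread was given as the SD of the 2 replicate lists. No test between the replicates was made, since a pair of libraries of the same group allows none, and no paired analysis was possible because there is 1 group.

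Chromosome lengths of the reference assembly GRCm38 were checked against the lists, and no interval reached past a chromosome end. Intervals on assembled chromosomes were used, and those on scaffolds were only counted. Genes were the 21938 protein-coding genes of GENCODE mouse release 21, with 93513 transcript starts. A promoter was marked when a replicated peak lay within 1000 bp of any transcript start of the gene. Peaks were assigned by midpoint to promoter, exon, intron or intergenic sequence in that order. Chance values came from 100 circular shifts of a list along its chromosomes. Promoter CpG content was the ratio of observed to expected CpG within 500 bp of the gene start, in 10 bins of genes.

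The gene lists were fixed before the data were examined, together with the motif strings, the tests and all but 1 of the alternatives. The 27 lists are limb patterning, limb signalling, posterior and anterior HoxA and HoxD genes, HoxB, HoxC, cartilage, bone, joint, tendon and fibroblast, skeletal muscle, epidermis, endothelium, erythroid cells, macrophages and leukocytes, Schwann cells and melanocytes, brain and neurons, liver, heart, pancreas and gut, pluripotency and germline, housekeeping, cell cycle, olfactory receptors, vomeronasal receptors, keratin-associated proteins and ribosomal proteins. Marking was tested with a two-sided Fisher's exact test against all other protein-coding genes. Covered bp within 10 kb of the gene start (list median) and distal peaks within 100 kb (list mean) were tested against 10000 random lists of the same size and promoter CpG bins. The smallest two-sided p these draws give is 0.0002. Adjusted p-values are Benjamini-Hochberg values over the 27 lists, with a threshold of 0.05. Members of a cluster share windows, which the random lists do not copy; keeping 1 member per 200 kb was added as an alternative after seeing the data.

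Distal peaks lay at least 2500 bp from any protein-coding transcript start. Windows of 1000 bp around their midpoints were searched on both strands for 26 consensus strings, 3 of them control strings written backwards. They were compared with flank windows 5 kb away that overlap no pooled peak, by a Mantel-Haenszel odds ratio and chi-square test over bins of 2% GC with a Robins-Breslow-Greenland 95% interval, and p-values were adjusted over the 26 strings. The 2 homeodomain strings written backwards were added after seeing the data and were not part of that adjustment. The cover of the HoxB cluster without its longest stretch free of HoxB genes was added after seeing the data. Domains were replicated peaks joined across gaps up to 1000 bp.

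The genes named were chosen by rule. For each list these were the 3 members with the most covered bp within 10 kb and up to 4 members without a marked promoter in alphabetical order. Genome-wide they were the genes at the 10 longest domains and the 10 genes with the most distal peaks, at least 200 kb apart. Hox genes that mark the ends of a peak or domain, and marked members given as examples of a list outside this rule, were chosen after their values were seen.

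The alternatives were the list of each replicate alone, the pooled list, replicated peaks with a q-value of 0.01 or less, promoter windows of 500 and 2500 bp, gene 5′ ends only, coverage windows of 5 and 25 kb, distal windows of 50 and 250 kb, random lists without CpG matching or matched on gene number, motif windows of 400 bp and flanks at 10 kb. For replicate overlap they were 50% of the peak, 50% of both peaks, the q limit and the 20000 peaks with the lowest p.

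The tests were tested on simulated data before use, with values simulated for the 21938 annotated genes. Fisher's exact test, the CpG-matched marking test and the distal test each called 100 of 100 planted lists, and the coverage test called 66 of 100. Of 170 lists with no planted effect, these tests called 4, 3, 0 and 0 (the last for coverage). Simulated lists were randomly drawn genes, with values independent between genes and marking that rose evenly with CpG decile. Real marking was 94.7% or more in deciles 6 to 10, and members of a cluster share windows. These call rates therefore do not carry over to clustered lists or to lists of high CpG content. On 13000 simulated windows the motif test called 4 of 4 planted strings and 0 of 22 others. Bases of these windows were drawn independently at a set GC content. The simulation therefore says nothing about base composition of real sequence beyond GC, where the backwards AP-1 and RUNX controls passed as depleted. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.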

Results

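Histone H3 dimethylated at lysine 4 (H3K4me2), a modification found at promoters and at distal regulatory elements, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the limbs of mouse embryos of 14.5 days. At this age the digits separate and the cartilage skeleton begins to be replaced by bone. Limbs of male and female embryos were pooled for each of 2 biological replicates, from 24 embryos for replicate 1 and 34 embryos for replicate 2. Both replicates form 1 group, and the labels give no other condition. The replicates could therefore be compared only with each other, and all other comparisons were made between genes and regions of the same genome. The deposited peak lists, on the mouse genome build mm10, held 50104 intervals for replicate 1 and 57930 for replicate 2. The list called from both replicates pooled held 52830 intervals, and the list of replicated peaks held 35182. Read counts were not analysed here, so the sequencing depth of each replicate is unknown, and all intervals given are for counts of peaks or genes. Fold values and peak p-values are the authors' own and were used only to describe or rank peaks within a list.

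The strongest H3K4me2 regions of the limb were found in both pools of embryos, and the replicates differed in their weakest peaks. Of the replicate 1 peaks, 69.3% overlapped a peak of replicate 2 (34705 of 50089 on assembled chromosomes). The overlap was 71.5% in the other direction (41429 of 57912). After lists were shifted along their chromosomes, these overlaps were 3.45% ± 0.140 and 3.18% ± 0.135 (SD over 100 shifts). The exact (Clopper-Pearson) 95% intervals were 68.9 to 69.7% and 71.2 to 71.9%. Bases covered in both replicates made up 68.7% of the bases covered in either, against 0.949% after shifting. Of the 20000 replicate 1 peaks with the lowest p, 19999 overlapped a replicate 2 peak, and all 20000 did in the reverse comparison. Among replicate 1 peaks of ranks 45001 to 50000, the overlap was 23.4%. When at least 50% of each peak had to be covered by the other, the overlap of replicate 2 fell to 46.6%.

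**Figure D1:**
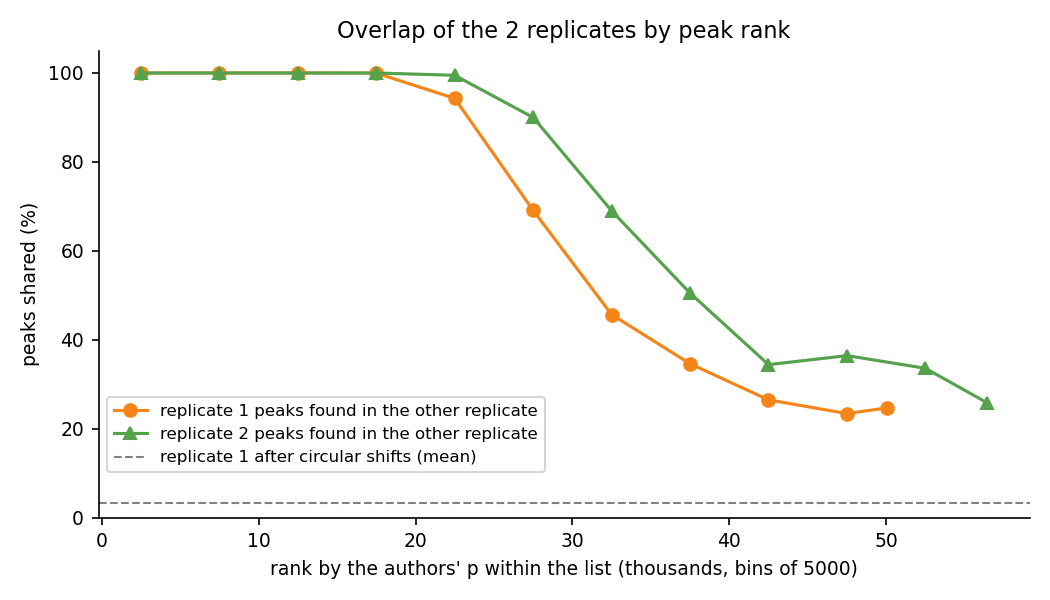
Percent of peaks of each replicate that overlap a peak of the other replicate (vertical axis) by rank of the authors' p-value in bins of peaks (horizontal axis, strongest peaks at the left), with the mean of replicate 1 after circular shifts as a broken line. Overlap is 100% for the strongest peaks in both replicates and falls to 23.4% at ranks 45001 to 50000 of replicate 1.

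Peaks found in 1 replicate only were narrow, weak and mostly away from promoters. In replicate 1, 15384 peaks (30.7%) had no overlap with replicate 2; their median width was 237 bp, against 971 bp for the shared peaks. Introns held 50.8% of them and promoters 10.8%, whereas promoters held 50.3% of the shared peaks. In replicate 2, 16483 peaks (28.5%) had no overlap with replicate 1, with a median width of 191 bp against 684 bp for the shared peaks. Promoters held 8.26% of these and 50.2% of the shared peaks. The authors' q-value was above 0.01 for 26.7% of the peaks found only in replicate 1 and for 48.7% of those found only in replicate 2. Replicate 2 had more intervals, by a ratio of 1.16, but its covered length was 42.6 Mb against 48.1 Mb in replicate 1. These differences rest on 1 library per side and have no p-value.

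Replicated H3K4me2 was concentrated at gene starts. Of 35167 replicated peaks on assembled chromosomes, 47.6% (16731) had their midpoint within 1000 bp of a protein-coding transcript start, 11.7-fold the 4.06% ± 0.197 (SD over 100 shifts) obtained after shifting. Exons held 6.17% of the peaks, introns 24.8%, and intergenic sequence 21.5% against 50.8% after shifting. The list covered 47.9 Mb, 1.81% of the sequenced bases, with a median peak width of 1034 bp. All 35167 peaks were also in the pooled list, and 2898 of them did not overlap a peak in both replicate lists. The 17648 pooled intervals outside the replicated list had a median width of 231 bp.

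The promoters of 14765 of 21938 protein-coding genes (67.3%, exact 95% interval 66.7 to 67.9%) carried a replicated peak within 1000 bp of a transcript start. The replicate lists marked 68.0% and 67.9% of the genes, and 383 genes were marked in exactly 1 of them. Marking followed the CpG content of the promoter closely. It was 6.20% in the decile of genes with the lowest ratio of observed to expected CpG dinucleotides and 99.4% in the decile with the highest. Gene lists fixed beforehand were therefore compared both with all other genes, by a two-sided Fisher's exact test, and with 10000 random lists of the same promoter CpG content. The random lists matched CpG content at the gene start only, whereas a peak at any transcript start counted as marking. The number of transcript starts per gene was not matched.

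Genes that pattern the limb and carry its signals had H3K4me2 at 1 or more transcript starts in every case. Fgf10, named after its values were seen, was marked at a transcript start but had 0 bp covered within 10 kb of its gene start. All 28 limb patterning genes were marked (exact adjusted p = 7.97e-05), among them Tbx5 of the forelimb, Pitx1 and Tbx4 of the hindlimb and Shh, the signal of the posterior limb margin. All 20 limb signalling genes were marked (exact adjusted p = 0.00148), such as Wnt5a, Fgfr2 and the retinoic acid receptor gene Rarg. The 10 posterior genes of the HoxA and HoxD clusters (group 8 and above), the 10 anterior genes of these clusters, the 10 HoxB genes and the 9 HoxC genes were also marked without exception. The adjusted p of each Hox list was 0.0494 by Fisher's exact test. It rose above 0.05 in 7 of the 8 other settings tried, for example to 0.0617 for the posterior genes with the replicate 2 list alone. None of these 6 lists passed against random lists of the same CpG content, where limb patterning had a permutation adjusted p of 0.139 and limb signalling 0.0846. Lists of that content had a median of 92.9% marked promoters for limb patterning. The 6 lists stood at 100%, the highest possible share. For limb patterning and the Hox lists the central range of random lists also reached 100%. These lists could not pass as above, so the test cannot decide whether they exceed their CpG content.

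Cartilage and tendon genes were marked more often than CpG-matched lists, and joint and bone genes did not pass this test. Of 22 cartilage genes, 21 were marked, including the regulator Sox9 and the collagen genes Col2a1 and Col9a3, against a median of 68.2% in CpG-matched lists (permutation adjusted p = 0.0027). Only Col10a1, the collagen gene of hypertrophic cartilage, was unmarked. Of 16 tendon and fibroblast genes, 14 were marked, including Scx, the tendon regulator, against 56.3% in matched lists (permutation adjusted p = 0.0185). Tnmd, a gene of mature tendon, and Kera were unmarked; Fisher's exact test of this list gave an adjusted p of 0.129. Of 10 joint genes, 9 were marked (exact adjusted p = 0.205; against a median of 90% in CpG-matched lists, permutation adjusted p = 1), and Prg4, which encodes the joint lubricant lubricin, was not. Among 16 bone genes, 11 were marked (exact adjusted p = 1; against 50% in CpG-matched lists, permutation adjusted p = 0.251), including the osteoblast regulators Runx2 and Sp7. The 5 unmarked bone genes were Bglap, Ibsp, Spp1, Dmp1 and Sost, which encode proteins of bone matrix and osteocytes; Spp1 was named after its value was seen.

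Genes of other cell types in the limb were marked in part. In skeletal muscle, 11 of 22 genes were marked (exact adjusted p = 0.129), against a median of 54.5% in CpG-matched lists. The unmarked ones included the contractile genes Acta1 and Actc1 and the regulator Myf5. Muscle marking depended on the list, with 14 genes marked in replicate 1 and 12 in replicate 2. In the pooled list 68.2% of the muscle genes were marked, close to the 68.5% of all genes there. Of 18 epidermal genes, 17 were marked (exact adjusted p = 0.0213), and Krt14, the keratin of the basal layer, was unmarked in the replicated list but marked in replicate 2. Trp63 and Krt5, named after their values were seen, were marked in the replicated and replicate 1 lists but not in replicate 2. The epidermal call was lost with the replicate 2 list alone (exact adjusted p = 0.112), with the 500 bp promoter window (0.0607), with 1 member per 200 kb (0.0823) and in CpG-matched lists (0.068). Of 16 endothelial genes, 10 were marked (exact adjusted p = 0.821); Sox17 and Erg were among them, and the junction genes Cdh5 and Pecam1 were not. Of 12 Schwann cell and melanocyte genes, 9 were marked (exact adjusted p = 0.821), and Plp1, Dct and Tyr were not. The marked Pmel starts (chromosome 10, 128704195) within 1000 bp of the start of the marked cell cycle gene Cdk2 (128705031). A peak there can count for both genes. Of 14 erythroid genes, 5 were marked (exact adjusted p = 0.034), including Klf1 and Tal1, and the alpha globin gene Hba-a1 was not. CpG-matched lists had the same share as the erythroid list, a median of 35.7% (permutation adjusted p = 1). In replicate 2 alone 7 were marked, and the erythroid call was lost there (exact adjusted p = 0.207) and with 1 member per 200 kb (0.276). None of 16 macrophage and leukocyte genes was marked (exact adjusted p = 9.11e-08; 25% in CpG-matched lists, permutation adjusted p = 0.0439), including Adgre1, Aif1, C1qa and C1qb.

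Several gene groups of other organs were marked less often than other genes. Of 18 liver genes, 3 were marked (exact adjusted p = 6.35e-05), with Alb and Afp, the serum albumin and fetal albumin genes, among the unmarked; CpG-matched lists gave a permutation adjusted p of 0.0785. Of 15 pancreas and gut genes, 5 were marked, against 60% in CpG-matched lists (permutation adjusted p = 0.0185). Their adjusted p by Fisher's exact test was 0.0213, and it was 0.138 with the replicate 2 list alone and 0.118 with the pooled list. Of 18 pluripotency and germline genes, 7 were marked, against 66.7% in matched lists (permutation adjusted p = 0.0185), and Nanog and Pou5f1 were unmarked. By the exact test the adjusted p of the germline list was 0.034, and 0.101 with 1 member kept per 200 kb. Heart genes were marked in 7 of 15 cases (exact adjusted p = 0.129), with the transcription factor gene Hand1 marked and the myosin genes Myh6, Myh7 and Myl7 unmarked. Brain and neuron genes formed the exception, with 17 of 18 marked (exact adjusted p = 0.0213; permutation adjusted p = 0.068 with CpG-matched lists, exact adjusted p = 0.0607 with the 500 bp window), and Neurod6 unmarked. Receptor families expressed in sensory neurons were almost free of H3K4me2. It marked 4 of 1092 olfactory receptor genes (0.366%) and 1 of 326 vomeronasal receptor genes (0.307%), each below CpG-matched lists (permutation adjusted p = 0.0018). Of 57 keratin-associated genes, which are expressed in the hair shaft, 1 was marked (exact adjusted p = 1.96e-25). Genes active in most cells were marked, with 20 of 20 housekeeping genes (exact adjusted p = 0.00148), 16 of 16 cell cycle genes (0.00641) and 79 of 82 ribosomal protein genes (8.42e-10). None of these 3 passed against CpG-matched lists. The housekeeping and cell cycle lists stood at 100%, which the central range of their random lists also reached, so they could not pass as above. Ribosomal protein genes had 96.3% against a median of 93.9% in matched lists (permutation adjusted p = 0.360).

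Of 27 lists, 12 were marked more often than other genes and 8 less often. With random lists of the same CpG content as the background, 2 lists were above and 6 below. The limb patterning, Hox, housekeeping and cell cycle lists, all at 100%, could not pass as above there. Members of a gene cluster share their surroundings and were counted as independent; with 1 member kept per 200 kb, a setting chosen after seeing the data, 7 lists were above. With the 500 bp promoter window 6 lists were above, with the replicate 2 list alone 7, and with the replicate 1 list, the pooled list or the 2500 bp window 8 each.

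**Figure D2:**
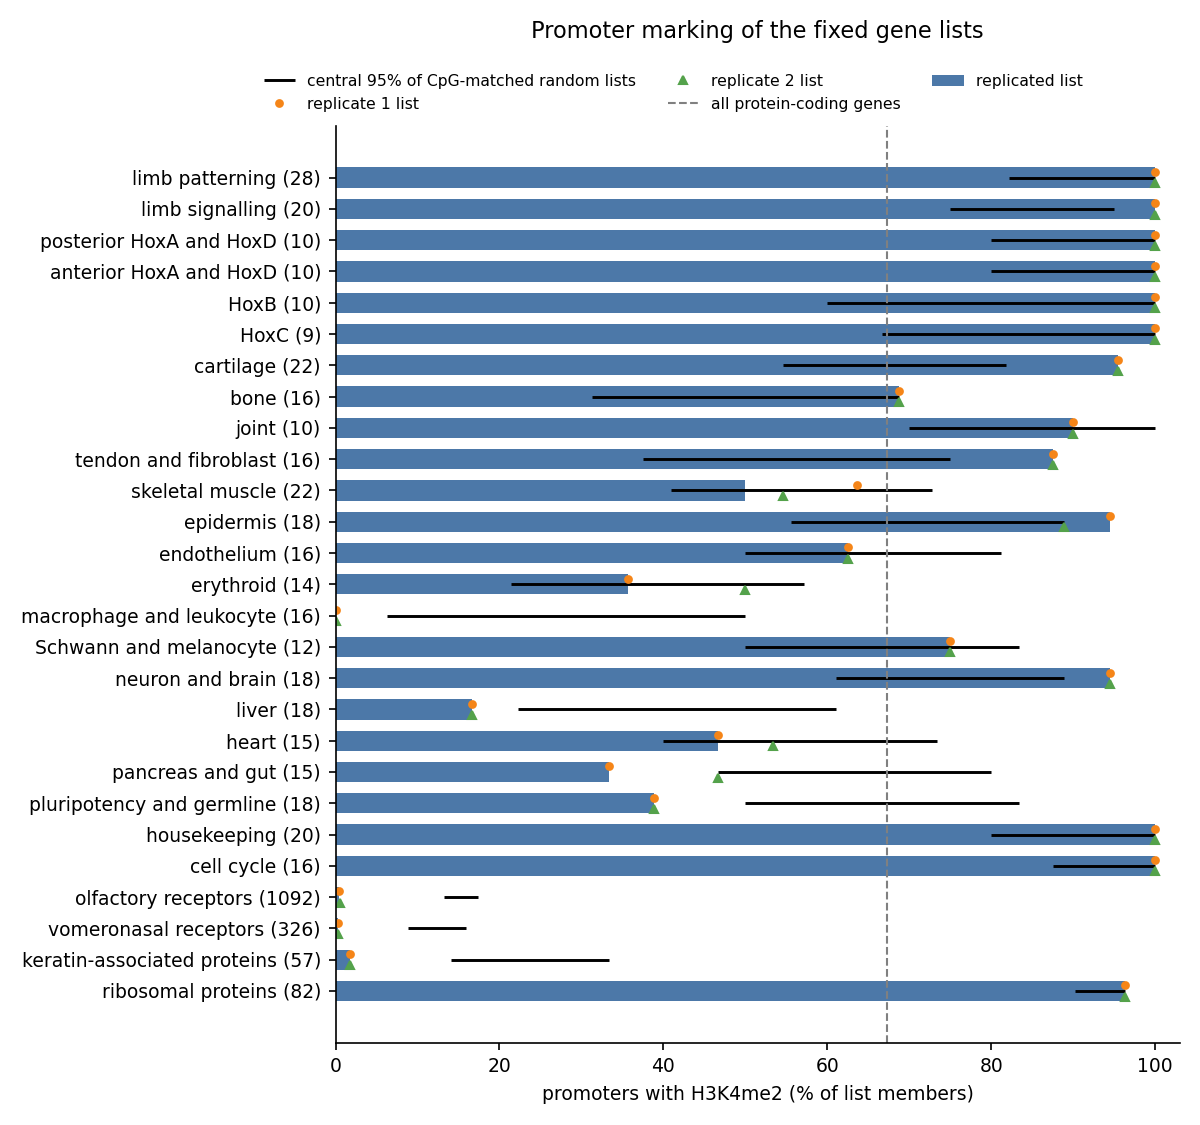
Percent of promoters in each gene list with a replicated H3K4me2 peak (bars), with the values of the 2 replicate lists (symbols), the central 95% of 10000 random lists of the same promoter CpG content (black lines) and the percent over all protein-coding genes (broken line); member numbers are in brackets. Limb patterning, limb signalling and Hox lists stand at 100%, and macrophage, olfactory and vomeronasal lists are at or near 0.

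The widest H3K4me2 coverage lay at posterior Hox genes and at limb patterning genes. Around the starts of posterior HoxA and HoxD genes, a median of 19978 bp was covered within 10 kb on either side (replicate lists 19408 ± 603 bp, SD, n = 2), where CpG-matched random lists had 2583.5 bp. The start regions of Hoxa9, Hoxa10 and Hoxa11, which pattern the upper and lower segments of the limb, were covered over all 20001 bp. Around limb patterning genes the median was 10954.5 bp (9942 ± 519 bp, n = 2), against 2392 bp in random lists. The most covered of them were Hand2 (chromosome 8, 57320983 to 57324633), which sets the posterior limb domain, with 16952 bp, Lmx1b (chromosome 2, 33560965 to 33640511), which sets dorsal identity, with 16769 bp, and Tbx5 with 13890 bp. Anterior HoxA and HoxD genes had a median of 9325 bp (8137 ± 1664 bp, n = 2), with Hoxa7, Hoxa3 and Hoxa6 highest. The gene model of Hoxa3 starts between Hoxa6 and Hoxa7, at 52213336. Hoxd3 and Hoxd4 share a start region (74711927 and 74711929) with 9325 bp each, so the median rests on that shared region. With 1 member kept per 200 kb the median was 4362.5 bp and the call was lost (permutation adjusted p = 0.467). The adjusted p of these 3 lists was 0.000771 by permutation, which corresponds to 0.0002, the smallest p that 10000 random lists can give.

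Signalling and skeletal genes were also covered more widely than CpG-matched lists. The median was 5904.5 bp for limb signalling genes, led by Rarg with 11972 bp, Wnt5a with 11098 bp and Axin2 with 10977 bp. It was 5458 bp for joint genes, led by Osr2 with 10385 bp, and 4049.5 bp for tendon and fibroblast genes, led by Pdgfra with 13211 bp. Cartilage genes had 3978.5 bp, led by Sox6 with 11765 bp, a partner of Sox9 in chondrocytes. The permutation adjusted p of these 4 lists was 0.000771. Bone genes had 3713.5 bp (permutation adjusted p = 0.0012), led by Col1a1, the main collagen gene of bone, with 13162 bp. HoxC genes had 6413 bp (permutation adjusted p = 0.0012) and HoxB genes 4318 bp (permutation adjusted p = 0.0072). Housekeeping genes had 4077 bp (permutation adjusted p = 0.0027), and ribosomal protein genes 3327.5 bp (permutation adjusted p = 0.00295). The housekeeping call was lost with a 25 kb window (permutation adjusted p = 0.0837), and the calls of ribosomal and HoxB genes with a 5 kb window (0.190 and 0.376).

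The other 15 lists did not pass against CpG-matched lists in coverage. For skeletal muscle, erythroid, macrophage, liver, heart, pancreas and gut, olfactory, vomeronasal and keratin-associated genes, the central range of random lists reached 0 bp. These lists could not pass as lower, so the test cannot decide whether they fall below their CpG content. In other settings skeletal muscle passed as higher with the pooled list (permutation adjusted p = 0.0428), germline as lower with a 5 kb window (0.0447) and cell cycle as higher without CpG matching (0.00405). Without CpG matching, olfactory, vomeronasal (permutation adjusted p = 0.00054 each) and keratin-associated genes (0.00249) passed as lower. Medians were 3672.5 bp for cell cycle genes (permutation adjusted p = 0.106), 2035.5 bp for epidermis, 1938 bp for Schwann cells and melanocytes, 1844 bp for skeletal muscle, 1754.5 bp for brain and 1662 bp for heart. They were 1446 bp for endothelium, 743 bp for germline (permutation adjusted p = 0.114), 502 bp for pancreas and gut, and 225 bp for erythroid genes. Medians were 0 for liver, macrophage, olfactory, vomeronasal and keratin-associated genes. The most covered muscle genes were Six1 (6462 bp), Lbx1 (6176 bp) and the contractile gene Tnnc2 (4586 bp), and the most covered epidermal gene was Tfap2a (11676 bp). The promoter of Tnnc2 was unmarked in the replicated list and in both replicate lists, so its covered sequence lay away from its own starts. Other muscle regulators, named after their values were seen, had 610 bp (Myod1), 1247 bp (Myog) and 0 bp (Mef2c). Myod1 and Mef2c were nevertheless marked at a transcript start, since coverage was measured around the gene start only. The random draws treat clustered genes as independent, and with 1 member per 200 kb the call of HoxB genes was lost too (permutation adjusted p = 0.608). The 1 HoxB member kept, Hoxb1, was the least covered of its list. It had 669 bp against 1835 bp in random draws, which turned the direction. The 2 posterior genes kept still had 19585.5 bp (permutation adjusted p = 0.00108).

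The Hox clusters differed in how much of their length was covered. HoxA (chromosome 6, 52155590 to 52260880) was covered over 70.0% of its length, with 69.1% in replicate 1 and 64.1% in replicate 2. HoxD (chromosome 2, 74668310 to 74765142) was covered over 50.6% (50.2% and 45.5%), and HoxC (chromosome 15, 102921103 to 103036852) over 41.1% (39.8% and 31.3%). HoxB (chromosome 11, 96194316 to 96368256), whose genes pattern the trunk, was covered over 13.9% (13.9% and 10.6%). HoxB includes 74.0 kb without a protein-coding HoxB gene, between Hoxb13 and Hoxb9, and without this stretch its cover was 20.3% (20.2% and 16.1%). The widest such stretch in the other clusters was 15.8 kb, in HoxC. The ranges spanned by the replicates did not overlap between clusters. In HoxA, 1 peak of 48.1 kb (52219213 to 52267308) ran from Hoxa7 past Hoxa13, the gene of the hand and foot; the longest peak of this stretch was 47.5 kb in replicate 1 and 11.3 kb in replicate 2. In HoxD, 1 peak of 37.9 kb ran from the sequence between Evx2 and Hoxd13 to Hoxd9; the longest peak there was 29.9 kb in replicate 1 and 16.3 kb in replicate 2. As single peaks both rest on the pooled calls, since replicate 2 had 8 pieces in the HoxA stretch and 7 in the HoxD stretch. The anterior ends, from Hoxa1 to Hoxa4 and from Hoxd3 to Hoxd1, carried separate short peaks.

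**Figure D3:**
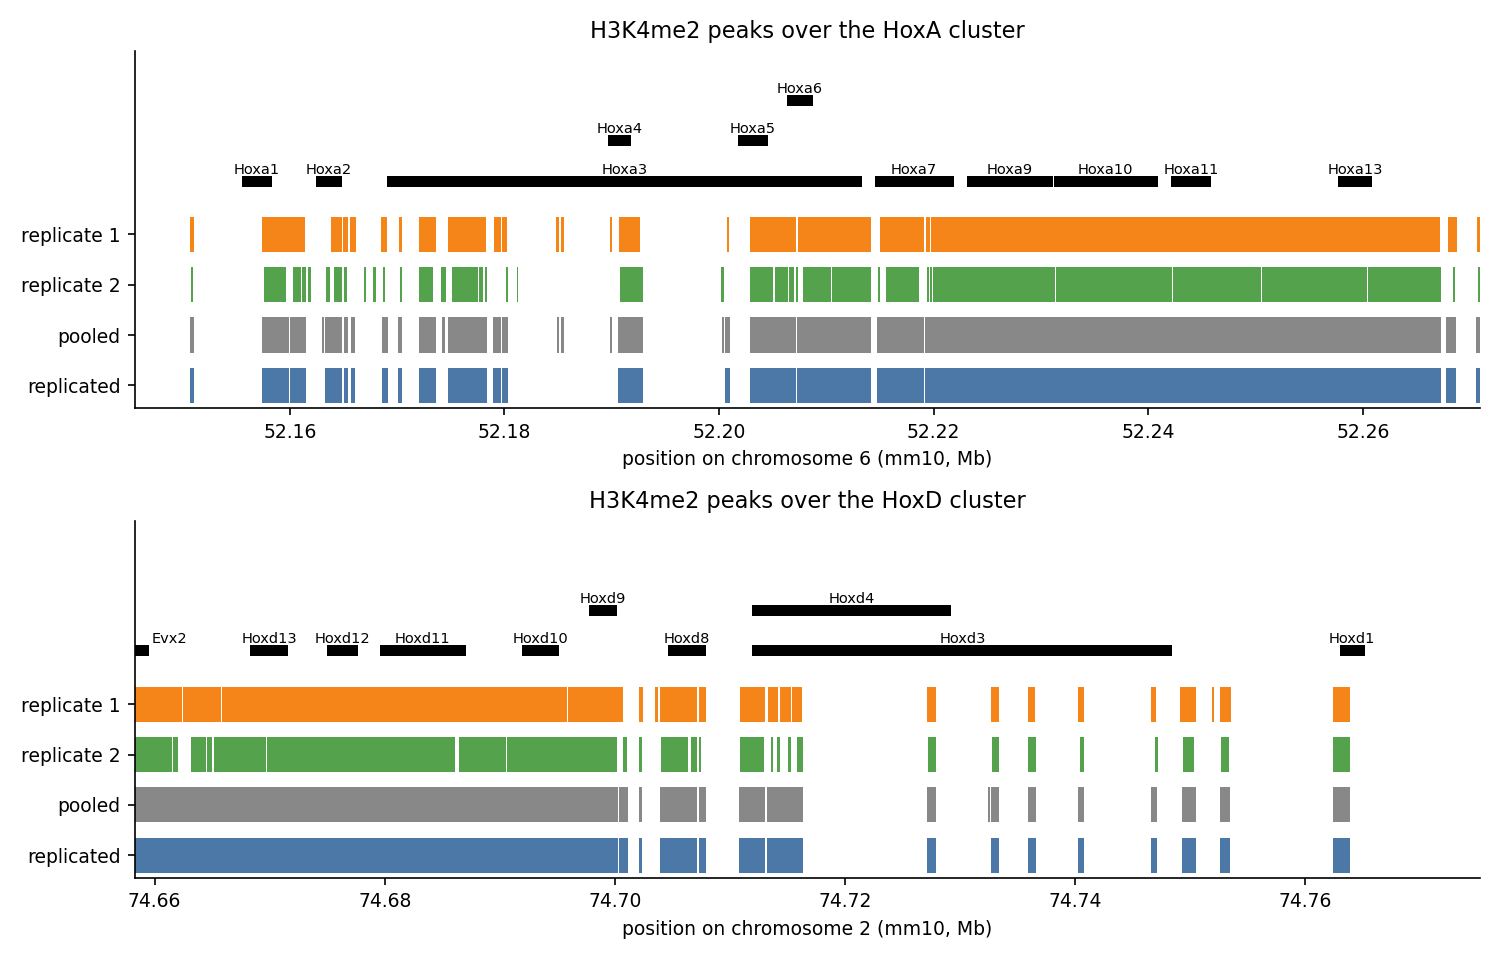
Maps of the HoxA cluster on chromosome 6 and the HoxD cluster on chromosome 2 (mm10 position in Mb on the horizontal axis), with genes as black bars and the intervals of the replicate 1, replicate 2, pooled and replicated lists as coloured bars. Near-continuous coverage spans Hoxa5 to Hoxa13, with breaks at Hoxa7, and Evx2 to Hoxd9, with a break between Evx2 and Hoxd13 in replicate 2, and shorter intervals lie at the anterior genes.

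The longest H3K4me2 domains of the genome, after joining replicated peaks across gaps up to 1000 bp, were those of HoxA and HoxD. Of 28800 domains, 893 exceeded 5 kb and 96 exceeded 10 kb. The HoxA domain (chromosome 6, 52202846 to 52268651) was 65.8 kb long and overlapped Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13; the gene model overlapped most was Gm28308. The HoxD domain (chromosome 2, 74648347 to 74702377) was 54.03 kb long and overlapped Evx2 and the genes from Hoxd13 to Hoxd9, most of all Hoxd11. Next came Ebf3 (27.0 kb, chromosome 7, 137296512 to 137323532), Zfhx3 (25.9 kb, chromosome 8, 108694953 to 108720896) and Nr2f2 (25.3 kb, chromosome 7, 70345632 to 70370959), all of which encode transcription factors. Lmx1b (21.7 kb, chromosome 2, 33626499 to 33648204), the Hedgehog receptor gene Ptch1 (20.3 kb, chromosome 13, 63554203 to 63574534), Bahcc1 (19.8 kb, chromosome 11, 120224264 to 120244043), Hand2 (18.6 kb, chromosome 8, 57316473 to 57335103) and Zfhx4 (18.1 kb, chromosome 3, 5209873 to 5227999) completed the 10 longest. The shortest length covered within any of them in a replicate list was 15.8 kb, at Zfhx4 in replicate 2. Joining gaps does not require unbroken signal, and the HoxA and HoxD domains held 64.6 kb and 51.9 kb of covered sequence.

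Distal H3K4me2 peaks, at least 2500 bp from any protein-coding transcript start, were concentrated around Hox and limb patterning genes. There were 15073 such peaks (42.9% of the replicated list). HoxC genes had a mean of 18.2 distal peaks within 100 kb of their starts, posterior HoxA and HoxD genes 11.3, anterior HoxA and HoxD genes 8.6 and HoxB genes 6.9. Limb patterning genes had 5.32, against 1.82 in CpG-matched random lists. Each of these 5 lists had a permutation adjusted p of 0.000771. Bone genes had 3.94 (permutation adjusted p = 0.00203), limb signalling genes 3.35 (0.0206), cartilage genes 3.18 (0.0184) and skeletal muscle genes 2.91 (0.031). The muscle call was lost with the replicate 2 list alone (permutation adjusted p = 0.0798) and with a 250 kb window (0.0881), where the cartilage call was lost too (0.156). The mean over all protein-coding genes was 1.57. Hox genes of a cluster share their windows, and with 1 member per 200 kb the calls of the anterior HoxA and HoxD list and of HoxB were lost (permutation adjusted p = 0.222 each). The single HoxC gene kept had 18 distal peaks (permutation adjusted p = 0.0171). The replicate lists held more distal peaks than the replicated list, 25246 and 28548, and gave limb patterning genes 9.91 ± 0.73 (SD, n = 2).

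Sensory receptor and hair genes had few distal peaks, with means of 0.197 for olfactory receptors, 0.221 for vomeronasal receptors (permutation adjusted p = 0.000771 each) and 0.439 for keratin-associated genes (0.0036). The keratin-associated call was lost with a 50 kb window (permutation adjusted p = 0.0810) and with 1 member per 200 kb (0.280). Joint genes had 3.70 (permutation adjusted p = 0.0619) and housekeeping genes 3.05 (0.0652), neither past the threshold, though each passed it in several other settings. The remaining lists did not pass by permutation; in other settings tendon and fibroblast genes passed with the pooled list (permutation adjusted p = 0.0231), macrophage and leukocyte genes with a 250 kb window (0.0048) and pancreas and gut genes with a 50 kb window (0.0374). Means were 2.56 for epidermis, 2.53 for pancreas and gut, 2.38 for tendon and fibroblasts, 2.38 for the cell cycle, 2.19 for endothelium and 2.17 for germline. They were 2.08 for Schwann cells and melanocytes, 2.06 for brain, 1.77 for ribosomal proteins, 1.6 for heart, 1.57 for erythroid cells, 1.44 for liver and 1.31 for macrophages and leukocytes. In all, 9 lists were above and 3 below.

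**Figure D4:**
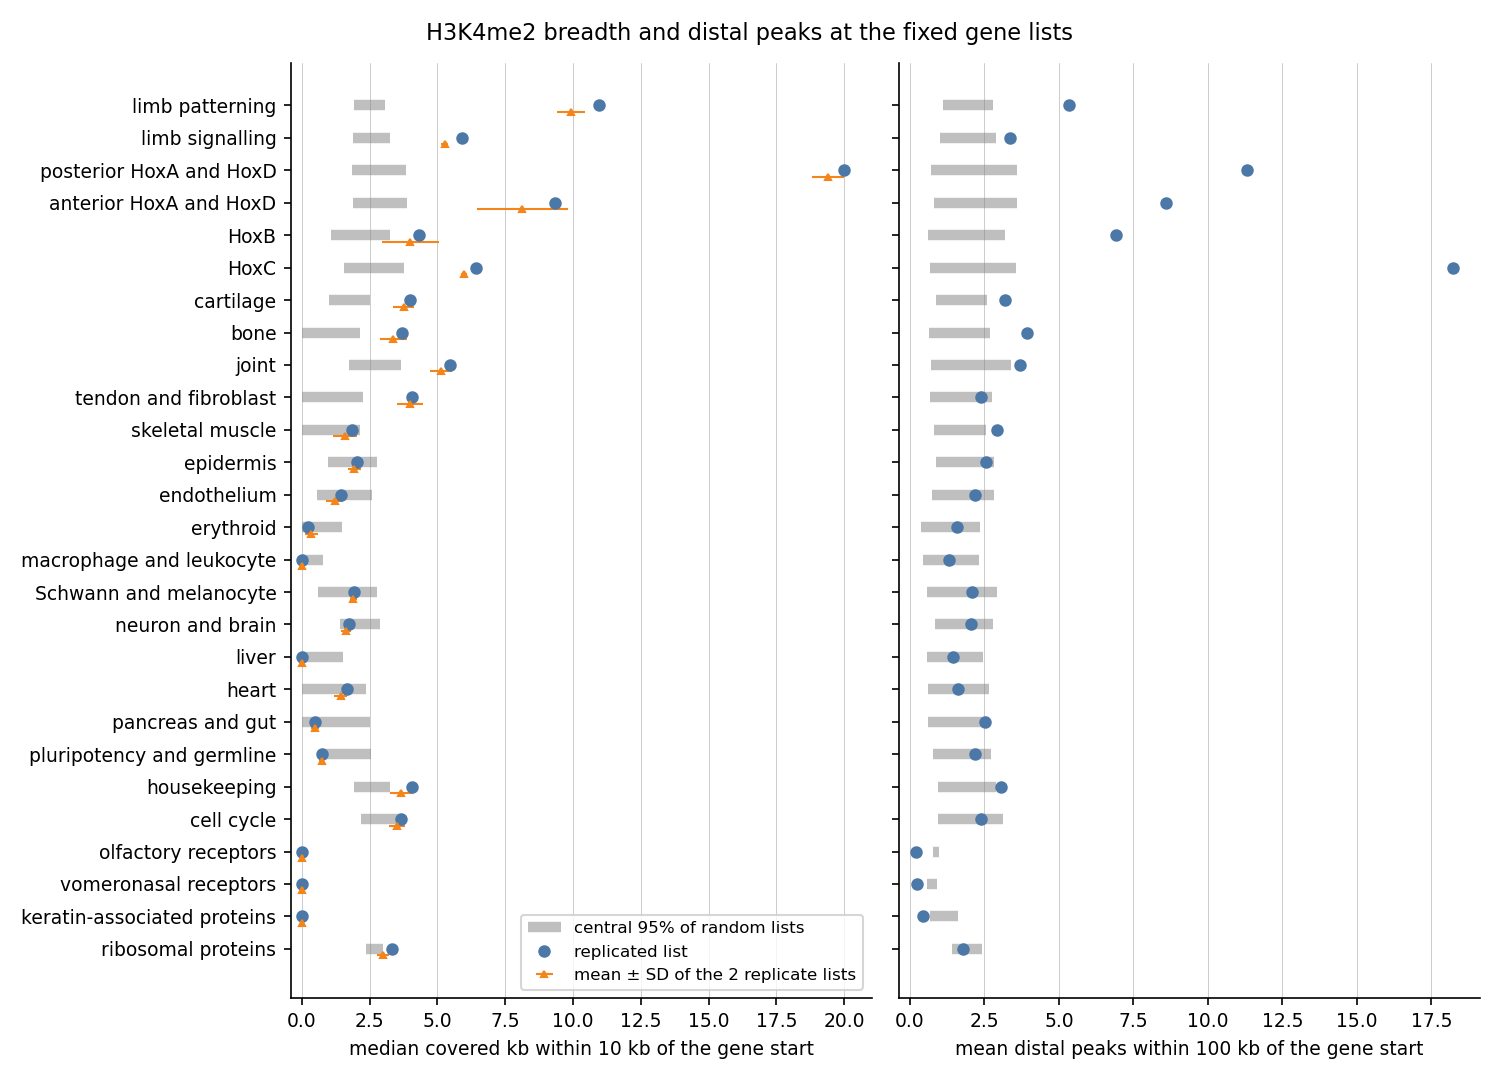
Left, median length in kb covered by replicated peaks within 10 kb of the gene start for each list (circles), with the mean and SD of the 2 replicate lists (triangles and lines) and the central 95% of CpG-matched random lists (grey bars). Right, mean number of distal peaks within 100 kb for the replicated list alone, with the same kind of random range; posterior Hox genes stand highest at the left with 19978 bp and HoxC genes at the right with 18.2 peaks.

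Among single genes, Btn2a2 and Hoxc4 had the most distal peaks of the replicated list within 100 kb, 22 each. Ahdc1 had 20, Irf2bpl 19, Pom121l2 19, Pax2 18, Lyl1 17, Trim27 17, 1700001O22Rik 16 and Acvr1b 16. The 95th percentile over all genes was 6. The order differed in the replicate lists. In replicate 1 Hoxc4 had 32, Lyl1 30 and Btn2a2 28, and in replicate 2 Ahdc1 and Lyl1 had 42 each, Hoxc4 36 and Btn2a2 34. Btn2a2, Pom121l2 and Trim27 lie in 1 stretch of chromosome 13 (21158145 to 23587359) that holds 104 annotated transfer RNA genes, and 53 of the 58 distal peaks around them were within 1 kb of such a gene. The windows of the other 7 genes held no annotated transfer RNA gene.

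Distal peaks carried short sequences bound by CTCF and by promoter-type factors more often than nearby unmarked sequence of the same GC content. Homeodomain strings were also more frequent within GC bins, but so were the posterior Hox and homeobox strings written backwards. The comparison set 15067 peak windows of 1000 bp against 24838 windows 5 kb away, in bins of 2% GC. The string of CTCF, which organises chromatin loops, was in 4.60% of peak windows and 0.878% of flanks (odds ratio 4.74, 95% interval 4.03 to 5.57). Odds ratios were 4.34 (2.42 to 7.80) for NRF1, 3.33 (3.05 to 3.64) for KLF and SP factors, 2.17 (1.76 to 2.68) for NFI and 2.05 (1.78 to 2.36) for ETS factors. Strings of muscle and growth regulators were also enriched, with 1.58 (1.34 to 1.85) for MEF2 and 1.37 (1.31 to 1.43) for the E-box of MyoD. For TEAD the ratio was 1.35 (1.28 to 1.43), and for TCF and LEF, which act in Wnt signalling, 1.19 (1.12 to 1.25). Among the enriched strings with an odds ratio given so far, only TEAD had a backwards control (1.06). Base composition beyond GC content was not tested for the others.

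The homeodomain strings had odds ratios of 1.49 (1.42 to 1.56) for posterior Hox proteins, 1.47 (1.305 to 1.65) for LHX and LMX proteins and 1.44 (1.38 to 1.51) for a general homeobox site. Without GC bins the posterior Hox string was less frequent in peak windows, 50.6% against 55.8% in flanks, as peak windows had a higher median GC content (49.1% against 44.8%). The same held for the general homeobox string (33.6% against 35.3%) and the LHX and LMX string (3.52% against 3.63%). The posterior Hox string written backwards, chosen as a control after seeing the data, had an odds ratio of 1.42 (1.35 to 1.48), and the backwards homeobox string, which keeps the TAAT core of the site, 1.51 (1.43 to 1.58). In all, 12 of 26 strings were enriched and 6 depleted. The largest adjusted p among the 12 was 1.53e-07 by the Mantel-Haenszel chi-square test, for NRF1. The depleted ones were PBX (0.818), AP-1 (0.861), GATA (0.870) and the E-box of Twist (0.932), and the backwards control strings of AP-1 (0.870) and RUNX (0.932). The Twist call was lost with the list of either replicate and with the pooled list, and turned with 400 bp windows (1.01). The PBX call was lost with 400 bp windows (0.875), and that of the backwards RUNX control with the replicate 2 list alone (0.964). RUNX (0.959), SOX (0.994), paired SOX (1.07), TFAP2 (1.03), p63 (1.02), MEIS (0.925), GLI (0.782) and backwards TEAD (1.06) did not pass in the main comparison. In other settings TFAP2 passed as enriched with the list of either replicate and with the pooled list (1.11), and GLI as depleted with 400 bp windows (0.589), flanks at 10 kb (0.775) and the replicate 2 list alone (0.809). With the replicate 2 list alone, paired SOX (1.12) and the backwards TEAD control (1.08) also passed as enriched.

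**Figure D5:**
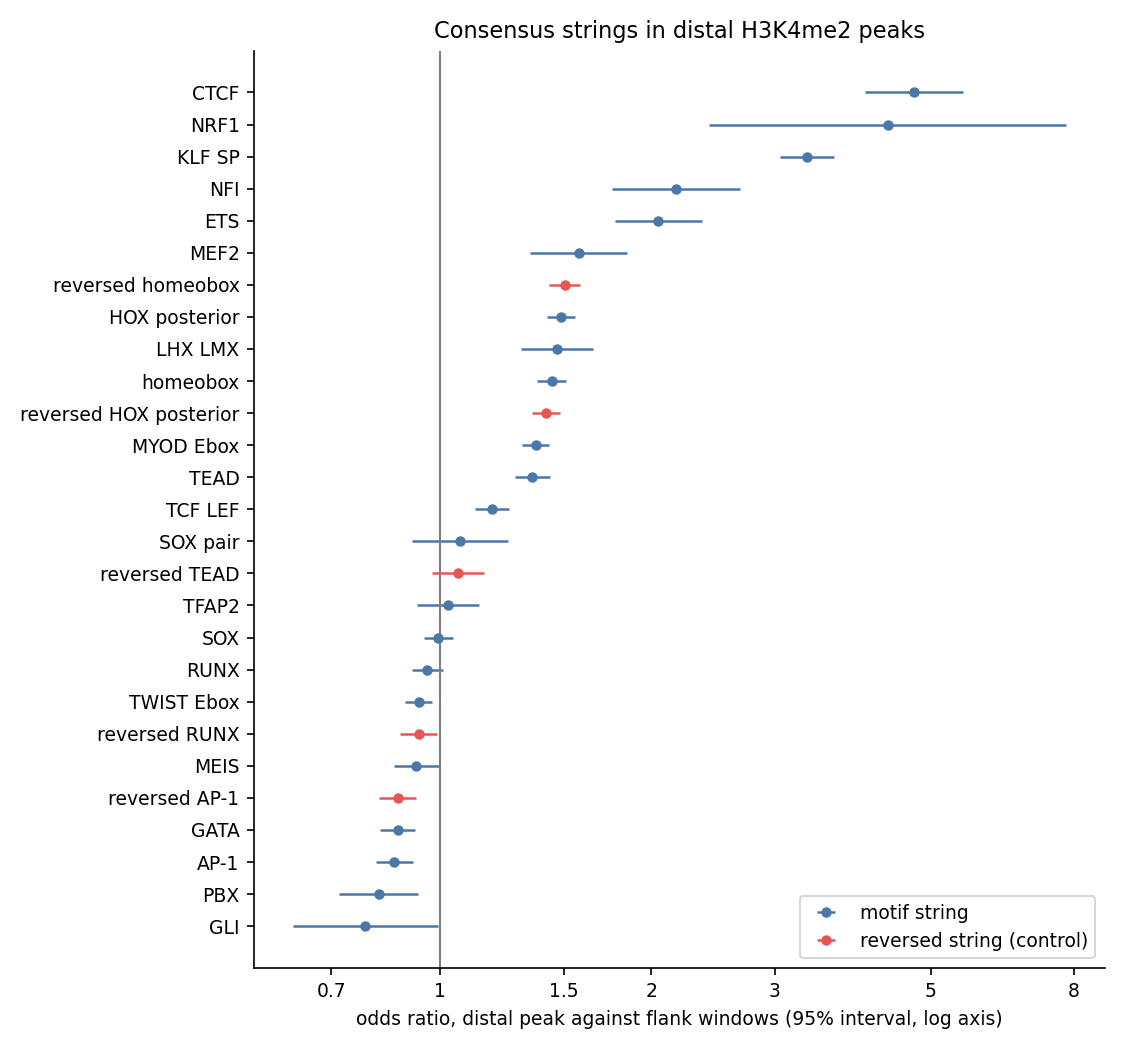
Odds ratio (points, log axis) with its 95% interval (lines) for each consensus string in distal H3K4me2 peak windows against flank windows of the same GC content; control strings written backwards are shown in their own colour and p63, with the widest interval (0.401 to 2.60), is left out. CTCF stands highest at 4.74, and the backwards posterior Hox string lies at 1.42 beside the forward string at 1.49.

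The X chromosome carried fewer H3K4me2 peaks for its length than any autosome. It had 5.87 replicated peaks per Mb, against 14.3 over the autosomes, which ranged from 10.1 on chromosome 14 to 22.6 on chromosome 11. The ratio of X to autosomes was 0.411 in the replicated list and 0.360 ± 0.0116 (SD, n = 2) in the replicate lists. Promoters were marked for 52.3% of X-linked genes and 68.6% of autosomal genes, with 1.01 and 1.64 peaks per protein-coding gene. The Y chromosome held 6 replicated peaks. Embryos of both sexes were pooled in each replicate.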

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

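The tests below were written before their results were computed, but their patterns, the 1.2 and 50% bounds and the backwards strings were chosen after seeing the data, and tests of 2 further patterns were dropped from the weighing after their results were known. Peaks on sequence outside the assembled chromosomes stood out as signal in data that no comparison used. The replicated list held 15 such intervals, 6 of them on a scaffold assigned to chromosome X, and the replicate lists held 15 and 18.

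Promoters of genes of other organs carried H3K4me2 in the limb, and CpG content of the promoters was tested as the explanation. Over the brain, heart, pancreas and gut, liver, and pluripotency and germline lists, 46.4% of 84 promoters were marked. CpG-matched random lists had 60.7% (central 95% 53.6 to 67.9%, permutation p = 0.0002, the smallest these draws give), and a share outside that range had been set beforehand as evidence against CpG content. That bound was wrong: a shortfall does not argue against CpG content at the promoters that are marked, and the pooled share mixes brain, with 94.4% against 77.8% in matched lists (permutation adjusted p = 0.068), and lists below theirs such as germline, with 38.9% against 66.7%. In each of these lists the marked promoters had a higher median ratio of observed to expected CpG than the unmarked ones. It was 0.570 against 0.206 for brain, 0.730 against 0.234 for pancreas and gut, and 0.504 against 0.332 for germline. These values go with CpG content, but they cannot separate it from cells of these lineages in the limb, which were not tested. CpG content as the reason for the marked promoters therefore stays open.

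The homeodomain strings were enriched in distal peaks, and the design gives no biological comparison for them. AT-rich base composition left over at matched GC content was tested with the posterior Hox string written backwards. Its odds ratio was 1.42 (95% interval 1.35 to 1.48), close to that of the forward string, 1.49 (1.42 to 1.56). Base composition may therefore account for most of the enrichment of the posterior Hox string, and binding by Hox proteins stays open. The LHX and LMX string had no such control, and the backwards homeobox string keeps the TAAT core, so base composition stays untested for both.

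Btn2a2, Pom121l2 and Trim27, among the 10 genes with the most distal peaks, lie in 1 stretch of chromosome 13. Transfer RNA genes, which are not among the protein-coding starts used to define distal peaks, were tested as the explanation. Of the 58 distal peaks around these genes, 91.4% lay within 1 kb of an annotated transfer RNA gene, so these peaks may mark transfer RNA promoters. No biological explanation was tested.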

How the results depend on the processing

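Keeping 1 list member per 200 kb was chosen after seeing the data; the other settings were planned. The overlap of replicate 1 peaks was 56.8% with 50% of the peak required, 53.9% with 50% of both peaks, 70.7% at a q-value of 0.01 or less and 90.0% for the 20000 peaks with the lowest p; for replicate 2 it was 66.2%, 46.6%, 80.1% and 98.9%. The share of peaks in promoters was 38.1 to 38.3% leaving out 1 replicate, 35.2% in the pooled list, 47.7% at the q limit, and 34.8% and 55.9% with 500 and 2500 bp windows. The intergenic share was 23.3 to 23.6% leaving out 1 replicate, 24.8% in the pooled list, and 23.2% and 20.5% with these windows. Marked promoters were 67.9 to 68.0% leaving out 1 replicate, 68.5% in the pooled list, 66.7% and 68.4% with these windows and 63.7% with gene 5′ ends only. The ratio of X to autosomes was 0.352 to 0.369 leaving out 1 replicate and 0.345 in the pooled list. The pooled and replicate lists include the weaker peaks that the replicated list leaves out.

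The number of lists with promoters marked above other genes was 12, and 12 at the q limit. It was 7 to 8 leaving out 1 replicate, 6 with the 500 bp window and 8 with the 2500 bp window. In the pooled list it was 8, with 1 member per 200 kb 7 and with CpG-matched lists 2. The limb patterning, Hox, housekeeping and cell cycle lists, all at 100%, could not pass as above CpG-matched lists. Lists below background in coverage were 0, 1 with a 5 kb window and 3 without CpG matching. In the main setting, lists whose central random range reached 0 bp could not pass as below. Of 831 values of single lists and strings under the alternatives, 741 kept their side of the threshold, 62 lost the call, 26 gained one and 2 reversed. A change of direction counted as reversed only where 1 of the values passed. The 2 were HoxB coverage with 1 member per 200 kb (669 bp) and the Twist E-box with 400 bp windows (1.01). The 741 include changes of direction between values that did not pass. Bone promoters, for example, were marked in 68.75% (all genes 67.3%), and in 62.5% (all genes 66.7%) with the 500 bp window. Of the 62, 46 concerned promoter marking, 7 distal peaks, 5 motifs and 4 coverage. Thinning leaves fewer members to test; otherwise the cause was not tested. Unknown depth limits what can be said about the weakest peaks, where the replicates overlapped least.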

Other observations

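The counts and tests in this part were chosen after the main results were seen, except the matching on gene number, which was fixed beforehand. The starts of 109 of 21938 protein-coding genes (0.497%) lay in an H3K4me2 domain longer than 10 kb. Among limb patterning genes 14 of 28 did: Hand2, Lhx9, Lmx1b, Msx1, Msx2, Pitx1, Prrx1, Ptch1, Sall1, Shox2, Tbx2, Tbx4, Tbx5 and Twist1. So did 9 of 10 posterior HoxA and HoxD genes, 4 of 10 anterior ones, 4 of 9 HoxC genes and, among 20 limb signalling genes, Axin2, Rarg and Wnt5a. The anterior ones include Hoxa3, whose gene model starts between Hoxa6 and Hoxa7. The HoxC genes include Hoxc5, whose gene model starts near the start of Hoxc10. The cartilage, bone, joint, tendon and epidermis lists had 1 member each, namely Sox6, Col1a1, Osr2, Pdgfra and Tfap2a. None of the members of the other lists, HoxB included, started in such a domain. Below the 10 longest domains stood those of Rarg (17.2 kb), Tfap2a (17.2 kb), Tbx5 (17.1 kb), Nfib (16.9 kb), Hoxc11 (16.2 kb) and Tbx15 (16.2 kb).

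Of 403 annotated transfer RNA genes, 258 (64.0%) had a replicated peak within 1 kb, with 64.5% in replicate 1 and 62.8% in replicate 2. After shifting, 4.18% ± 2.02 (SD over 100 shifts) did, at most 12.2%. Of the 323 transfer RNA genes at least 3.5 kb from a protein-coding start, 188 (58.2%) had a peak. Over the genome, 155 of 15073 distal peaks (1.03%) lay within 1 kb of a transfer RNA gene.

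Tests of 2 further patterns were also run and were dropped from the weighing after their results were known. The first, a comparison of ratios without a p-value, was the larger number of peaks in replicate 2. The ratio of replicate 2 to replicate 1 was 1.16 for intervals and 1.09 after joining across 1 kb. It was 1.03 for intervals with a q-value of 0.01 or less and 0.885 for covered length. The other was the number of distal peaks around limb genes: random lists matched on the number of genes within 100 kb left limb patterning genes above background in distal peaks, with a permutation adjusted p of 0.000675.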
